A study of Mus musculus with 24 samples.

How the data were processed

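RNA of cultured mouse AGM cells was measured on 24 Illumina bead arrays in 8 groups of 3, defined by flow (static or WSS), drug (vehicle or indomethacin) and time (6 h or 36 h). Group and replicate were taken from the sample titles. Each sample pooled 6 channels of the same treatment, per the labels, which do not say whether the 3 samples of a group came from separate cultures or animals. The p-values therefore measure the spread between these samples, which may be technical. Replicate numbers recur across groups, and no pair of arrays held identical values.

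The deposited signal table gives an intensity per probe on a linear scale, per the file headers, without background subtraction or normalization between arrays. The deposited detection p-values stand beside each signal, per the file headers, and rise in equal steps from 0 to 1, read here as the share of negative control beads at or above the signal. The authors prepared biotinylated cRNA with an Ambion MessageAmp kit, per the labels' protocols. The software that exported the signals is not given in the sources used here. A second deposited table holds the authors' processed intensity values. Set against the signals of the same arrays, these were linear, background-subtracted and quantile normalized, with column medians of 11.6 to 11.7. They were floored at 16 before log2 was taken. How the background was subtracted stays unknown.

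In R 4.3.3 with limma 3.58.1, the signals were corrected by neqc, which fits a normexp background to negative controls inferred from the detection p-values, adds an offset of 16, quantile normalizes and takes log2. A change on this scale is smaller than the true change for dim probes, because of the offset. A probe was kept if its detection p was under 0.05 on all 3 arrays of at least 1 group, which held for 21251 of 45281 probes. The platform table pairs 35784 probes with 1 gene symbol, 0 with several and lists none for 9497. Symbols were updated through the Entrez ID for 28620 probes and through the accession for 2637, using a RefSeq gene table of assembly GRCm38.p6, and kept as given for 4527, so that 937 changed. No genome build is named for the arrays, so no coordinates are given. Of the detected probes 18242 had a symbol and 3009 did not. The probe with the highest mean over all arrays stood for a gene, which left 12226 genes, 4145 of them with at least 2 detected probes. Among passing genes with other detected probes, all probes changed with the same sign in 1129 of 1351 genes (WSS against static in vehicle at 6 h), 342 of 387 (at 36 h) and 1861 of 2230 (36 h against 6 h in static vehicle).

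All 24 arrays entered 1 linear model with a mean per group (lmFit, contrasts and eBayes), which left 16 residual degrees of freedom, or 21.5 in total after eBayes. There were 12 comparisons. They were WSS against static in each drug state and time, indomethacin against vehicle in each flow state and time, the flow by drug interaction at each time, the flow by time interaction in vehicle, and time in static vehicle culture. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes. No exact test of 3 arrays against 3 can go below p = 0.1, so genes were tested in limma alone. Tests are 2-sided. There were 31 gene lists, with 476 genes in all, tested with camera at a preset correlation of 0.01 and adjusted over lists and comparisons together. All list calls were lost when the correlation between genes was estimated. As an alternative, fry tested whether the genes of a list moved one way on balance. Overlaps of passing genes were tested with Fisher's exact test.

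Genes were named by a rule set, like the groups, tests, lists and most alternatives, before the data were examined. It took passing genes whose 3 arrays in one group all lay beyond those of the other (for an interaction, passing genes). Named were the 8 largest rises and 8 largest falls for WSS against static in vehicle and for indomethacin under WSS, and 4 and 4 elsewhere. Where none passed, the 3 smallest p-values were named. Up to 4 passing members of each list by size of change and a fixed panel of genes of flow, prostaglandins, blood formation and endothelium were added. Clones and predicted genes without a name were passed over for the next gene. Not all genes that the rule takes are printed.

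The fit alone was tested on simulated gene values for WSS against static in vehicle at 6 h. Of 12226 genes 200 were changed, and a list was shifted downward by 0.5. The fit recovered 31.3% of changes of 0.5 on the log2 scale, 85.1% of those of 1 and 100% of those of 2. Of 156 genes called, 11 were unchanged. Alternatives were no background correction, an offset of 50, median scaling, the processed values, no filter on dim probes or a detection p under 0.01, all detected probes, only the arrays compared, array weights, trend and robust eBayes, the replicate number as a block, and each array left out. Normalization without WSS vehicle array 2 at 36 h and without WSS indomethacin array 2 at 6 h was added after seeing the data. The slide of each array is not given by the files or labels, so slide could not be tested.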

Results

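Gene expression was measured in cells of the mouse aorta-gonad-mesonephros (AGM), the embryonic region around the dorsal aorta from which blood stem cells emerge. Cells dissociated from C57BL/6J embryos at day 10.5 of gestation were cultured in microfluidic channels for 6 h or 36 h. The medium was either nearly still, at 1e-04 dyne per cm2 (static), or gave a wall shear stress (WSS) of 5 dyne per cm2. It held vehicle or 10 uM indomethacin, a cyclooxygenase inhibitor. The 8 groups held 3 arrays each, 24 in all, and each sample pooled 6 channels. The comparisons address which transcripts shear stress changes in these cells, early and late, and whether inhibition of prostaglandin synthesis alters that response.

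Between 18681 and 22156 of 45281 probes per array were detected above background, or 41.3 to 48.9%, and the number of arrays limits the precision. The mean signal before normalization ranged from 370 to 610.4. At 6 h it averaged 409.7 in static and 542.95 in WSS arrays, and at 36 h 475.22 and 533.95. After normalization, arrays correlated at 0.98 to 0.993 within groups and at 0.928 to 0.993 between groups. On the second principal component (16.7% of the variance) WSS vehicle array 2 at 36 h lay at -5.15, and the other arrays of its group at -12.21 and -14.34. Log2 fold changes are given ± SE (variance pooled over all groups), with Benjamini-Hochberg adjusted limma p-values over 12226 genes. A change is also written as at least N-fold where the probe was not above background on any of the 3 arrays of the dimmer group. The N sets the brighter group's mean against the lowest detected signal on those arrays or, where higher, the probe's own.

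**Figure D1:**
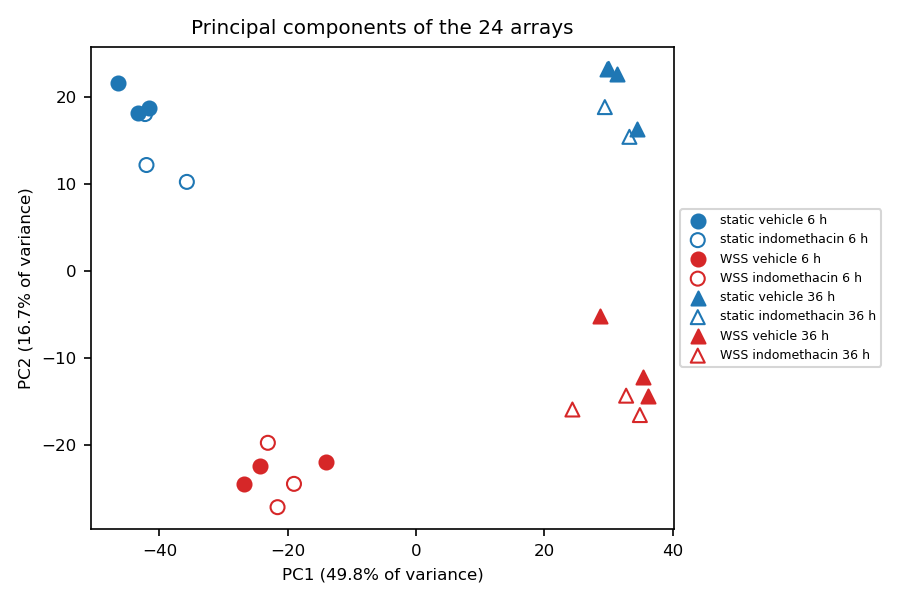
Each point is 1 of the 24 arrays, placed by its scores on the first principal component (49.8% of the variance) and the second (16.7%) of the normalized log2 values, in the units of those scores. Colours and symbols mark the 8 groups of 3 arrays, and WSS vehicle array 2 at 36 h (-5.15 on the second component) lies apart from the other arrays of its group at -12.21 and -14.34.

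Transcripts of the response to low oxygen and of glycolysis were lower under 6 h of shear stress without drug. Of these, 0 of 15 tested genes rose, 15 fell and 0 did not pass (0 and 15 adjusted over the list alone, camera adjusted p = 7.4e-20, adjusted p = 0.17 with an estimated correlation). Its median log2 fold change was -2.34. Pdk1, a kinase that restrains pyruvate use by mitochondria, was 12.8-fold lower and the glucose transporter gene Slc2a3 11.4-fold lower. The largest falls were in Mgarp (-3.85 ± 0.43, adjusted p = 2.3e-06), Car9 (-3.71 ± 0.2, at least 9.63-fold, adjusted p = 1.9e-10), Pdk1 (-3.68 ± 0.37, adjusted p = 7.9e-07) and Slc2a3 (-3.51 ± 0.24, adjusted p = 4.1e-09). They were followed by Hspa1a (-2.89 ± 0.67), Bhlhe40 (-2.84 ± 0.23), Pfkl (-2.83 ± 0.22) and Stc2 (-2.83 ± 0.26), with adjusted p of at most 0.0028. Car9 encodes a carbonic anhydrase induced in low oxygen, Hspa1a an inducible heat shock protein and Pfkl a phosphofructokinase. Other members of the hypoxia list fell, including Egln3 (-2.78 ± 0.26) and Ndrg1 (-2.71 ± 0.31), with adjusted p of at most 2.7e-06. Egln3 is a prolyl hydroxylase that acts on hypoxia-inducible factors. Gapdh, a glycolytic enzyme often used as a control, also fell (-0.69 ± 0.12, adjusted p = 0.00022). For Car9 the log2 fold change was -2.36 with no background correction.

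The largest rises at 6 h were in Acod1 (2.55 ± 0.4, at least 4.72-fold, adjusted p = 9.8e-05), Ccl5 (1.87 ± 0.51, at least 2.86-fold, adjusted p = 0.0092), Clec4d (1.85 ± 0.41, at least 3.17-fold, adjusted p = 0.0018) and Pcp4l1 (1.76 ± 0.21, adjusted p = 4.8e-06). They were followed by Gdf10 (1.75 ± 0.36), Cd14 (1.72 ± 0.31), Trim10 (1.66 ± 0.48) and Cxcl2 (1.64 ± 0.4, at least 2.58-fold), with adjusted p of at most 0.012. Acod1 makes itaconate in macrophages, Ccl5 and Cxcl2 are chemokines, Clec4d is a myeloid lectin and Cd14 a receptor for bacterial lipopolysaccharide. For these genes and the largest falls, all 3 arrays of one group lay beyond all 3 of the other. In the macrophage and myeloid list, 4 of 15 tested genes rose, 0 fell and 11 did not pass (4 and 0 adjusted over the list alone, camera adjusted p = 0.42). Its leading members were Cd14 and the lysozyme gene Lyz2 (1.62 ± 0.38, adjusted p = 0.003). In the inflammatory list, 4 of 11 tested genes rose, 2 fell and 5 did not pass (6 and 2 adjusted over the list alone, camera adjusted p = 0.51). Its leading members were Cxcl2 and Saa3 (1.39 ± 0.51, adjusted p = 0.043), an acute phase protein gene. Ccl5 lost its call without WSS array 1 (adjusted p = 0.087). Trim10 lost its call without static array 2 or 3 or WSS array 1 (adjusted p up to 0.059). Saa3 lost its call without static array 2 or 3 or WSS array 1 or 2 (adjusted p up to 0.28). Without WSS array 1 the log2 fold change was 1.19 for Ccl5 and 0.78 for Saa3. With no background correction log2 fold changes were Acod1 1.47, Ccl5 1.06, Clec4d 1, Cd14 0.91, Cxcl2 0.87, Lyz2 0.9 and Saa3 0.77. With an offset of 50 they were Acod1 1.64, Ccl5 1.18, Clec4d 1.15, Cd14 1.08, Cxcl2 0.98, Lyz2 1.07 and Saa3 0.84. Ccl5 and Saa3 did not pass with array weights. Saa3 did not pass with an offset of 50, median scaling, the processed values, no filter on dim probes or trend and robust fitting.

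Immediate early genes, which respond within minutes to growth factors and stress, were lower after 6 h of flow. In that list, 0 of 15 tested genes rose, 10 fell and 5 did not pass (0 and 12 adjusted over the list alone, camera adjusted p = 8.4e-05, adjusted p = 0.65 with an estimated correlation). They were led by Ier3 (-1.67 ± 0.27, adjusted p = 0.00012) and Fos (-1.42 ± 0.32, adjusted p = 0.002). Genes driven by the oxidative stress factor NRF2 were higher. Among its members, 5 of 14 tested genes rose, 0 fell and 9 did not pass (6 and 0 adjusted over the list alone, camera adjusted p = 0.0053, adjusted p = 0.78 with an estimated correlation). The quinone reductase gene and a gene of glutathione synthesis led them, Nqo1 (1.52 ± 0.33, adjusted p = 0.0017) and Gclm (1.42 ± 0.23, adjusted p = 0.00016). Targets of YAP, a factor that responds to mechanical tension, were lower. Within the list, 0 of 11 tested genes rose, 4 fell and 7 did not pass (0 and 5 adjusted over the list alone, camera adjusted p = 0.044, adjusted p = 0.9 with an estimated correlation). The leading members were Ccn1 (-1.16 ± 0.2, adjusted p = 0.00026) and Amotl2 (-0.95 ± 0.24, adjusted p = 0.0046). Each camera test ranked a list against the other genes tested. The YAP list lost its call without static array 3 or WSS array 1 or 3 (camera adjusted p up to 0.095). With fry the adjusted p was 0.066 for the YAP list. Nqo1 had a log2 fold change of 0.8 with no background correction and 0.97 with an offset of 50.

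Among genes of blood stem cells and their emergence, 5 of 16 tested genes rose, 1 fell and 10 did not pass (5 and 1 adjusted over the list alone, camera adjusted p = 0.46). Gata2 and Tal1, transcription factors of early blood formation, rose, and Kit, a receptor on blood progenitors, fell. Their values were Gata2 (1.11 ± 0.23, adjusted p = 0.0013), Tal1 (1.01 ± 0.27, adjusted p = 0.0068) and Kit (-0.65 ± 0.17, adjusted p = 0.0067). No call was made for Runx1 (0.18 ± 0.26) and Itga2b (-0.09 ± 0.22), with adjusted p of at least 0.64. Among genes induced by laminar flow in endothelium, 1 of 16 tested genes rose, 3 fell and 12 did not pass (1 and 2 adjusted over the list alone, camera adjusted p = 0.57). Thbd, which encodes thrombomodulin, led the falls, Thbd (-1.87 ± 0.38, adjusted p = 0.0011). No call was made for Klf2 (0.04 ± 0.45), Klf4 (-0.62 ± 0.25), Nos3 (0.1 ± 0.21), Hmox1 (0.77 ± 0.35) and Cyp1b1 (-0.27 ± 0.19), with adjusted p of at least 0.067. In the endothelial list, 0 of 18 tested genes rose, 1 fell and 17 did not pass (0 and 0 adjusted over the list alone, camera adjusted p = 0.99). The median was 0.09 and the mean 0.02, with the test towards lower values. Junction genes that did not pass were Cdh5 (0.3 ± 0.26) and Pecam1 (-0.06 ± 0.21), with adjusted p of at least 0.42. Tal1 lost its call without static array 3 (adjusted p = 0.054). Kit lost its call without static array 2 (adjusted p = 0.05). Tal1 had a log2 fold change of 0.5 with no background correction and 0.56 with an offset of 50.

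Among genes of prostaglandin synthesis and its receptors, 2 of 9 tested genes rose, 0 fell and 7 did not pass (2 and 0 adjusted over the list alone, camera adjusted p = 0.49). The prostaglandin E synthase genes Ptges2 (0.89 ± 0.19, adjusted p = 0.0017) and Ptges3 (0.73 ± 0.13, adjusted p = 0.00023) rose. No call was made for Ptges (0.29 ± 0.25) and Hpgd (0.45 ± 0.26), with adjusted p of at least 0.2. Among targets of cyclic AMP signalling, 1 of 14 tested genes rose, 4 fell and 9 did not pass (1 and 5 adjusted over the list alone, camera adjusted p = 0.27). The phosphodiesterase gene Pde4b fell and the repressor gene Crem rose, Pde4b (-1 ± 0.23, adjusted p = 0.0024) and Crem (0.54 ± 0.15, adjusted p = 0.012). Ptgs2, Ptger2, Ptger4, Nr4a1, Myb, Ptprc, Dll4 and Cyp1a1 were not detected on all 3 arrays of any group, and no probe was listed for Ptgs1. In total 3592 of 12226 genes passed, 1840 higher and 1752 lower, which is 51.2% higher, or 41.1% with median scaling. All arrays of one group lay beyond those of the other for 5606 genes, or 45.9%, against 10% by chance. Crem lost its call without static array 2 or 3 (adjusted p up to 0.078). For Crem the log2 fold change was 0.35 with no background correction. Crem did not pass with median scaling or with only the arrays compared.

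After 36 h of flow without drug the hypoxia and glycolysis list was lower. By gene, 0 of 15 tested genes rose, 14 fell and 1 did not pass (0 and 14 adjusted over the list alone, camera adjusted p = 1.3e-31, adjusted p = 0.056 with an estimated correlation). Its median log2 fold change was -2.01. The largest falls were in Car9 (-4.08 ± 0.2, at least 13.7-fold, adjusted p = 2.7e-11), Mgarp (-4.05 ± 0.43, adjusted p = 1.8e-06), Pdk1 (-3.69 ± 0.37, adjusted p = 1e-06) and H2-Ab1 (-3.3 ± 0.28, adjusted p = 9.1e-08). They were followed by Tmem45a (-3.17 ± 0.35), Lox (-3.01 ± 0.36), Pygl (-2.75 ± 0.2) and Aldoc (-2.65 ± 0.24), with adjusted p of at most 8.9e-06. H2-Ab1 encodes a chain of major histocompatibility complex class II, Lox an enzyme that crosslinks collagen, Pygl a glycogen phosphorylase and Aldoc a glycolytic aldolase. The largest rises were in Dct (2.02 ± 0.36, adjusted p = 0.0012), Matn4 (1.82 ± 0.23, adjusted p = 2.6e-05), Il11 (1.79 ± 0.28, adjusted p = 3e-04) and Uts2b (1.77 ± 0.34, adjusted p = 0.0024). They were followed by Hmox1 (1.73 ± 0.35), Zfp365 (1.7 ± 0.3), Hap1 (1.68 ± 0.2) and Ass1 (1.67 ± 0.27), with adjusted p of at most 0.0035. Dct is an enzyme of melanin synthesis, Matn4 a matrix protein, Il11 a cytokine, Hmox1 haem oxygenase 1 and Ass1 an enzyme of arginine synthesis. All 3 arrays of one group lay beyond all 3 of the other for each of these genes. Without WSS array 1 the log2 fold change was 1.12 for Hmox1. Log2 fold changes with no background correction were Car9 -2.7, Aldoc -1.72, Matn4 1.07, Il11 0.99 and Uts2b 1.05. With an offset of 50 Il11 had 1.17. Lox, Dct, Il11, Hmox1, Zfp365 and Ass1 did not pass with only the arrays compared.

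Genes of mesenchyme and matrix were lower at 36 h. Counted singly, 0 of 15 tested genes rose, 6 fell and 9 did not pass (0 and 8 adjusted over the list alone, camera adjusted p = 1e-05, adjusted p = 0.13 with an estimated correlation). After Lox, the largest fall was in the mesenchymal receptor gene Pdgfra (-1.24 ± 0.34, adjusted p = 0.025). Markers of neurons and neural crest were higher. Of its members, 4 of 9 tested genes rose, 1 fell and 4 did not pass (5 and 1 adjusted over the list alone, camera adjusted p = 0.048, adjusted p = 0.71 with an estimated correlation). Examples were Stmn2 (1.19 ± 0.27, adjusted p = 0.0071) and Nefm (1.13 ± 0.24, adjusted p = 0.0056), genes of the neuronal cytoskeleton. Targets of p53, the factor that responds to DNA damage, were higher. Of these, 4 of 9 tested genes rose, 0 fell and 5 did not pass (7 and 0 adjusted over the list alone, camera adjusted p = 0.00031, adjusted p = 0.55 with an estimated correlation). The cell cycle inhibitor gene Cdkn1a and Trp53inp1 led them, Cdkn1a (1.18 ± 0.22, adjusted p = 0.002) and Trp53inp1 (0.98 ± 0.17, adjusted p = 9e-04). The neural list lost its call without static array 1 or 3 or WSS array 2 (camera adjusted p up to 0.13). Pdgfra lost its call without static array 1 or 2 or WSS array 1 or 3 (adjusted p up to 0.15). Stmn2 lost its call without static array 3 (adjusted p = 0.056). Without WSS array 3 the log2 fold change was -0.74 for Pdgfra. Pdgfra, Stmn2, Cdkn1a and Trp53inp1 did not pass with only the arrays compared.

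Targets of NRF2 were also higher at 36 h. In that list, 4 of 14 tested genes rose, 0 fell and 10 did not pass (5 and 0 adjusted over the list alone, camera adjusted p = 0.0027, adjusted p = 0.75 with an estimated correlation). Leading the list were Hmox1 and Nqo1 (1.33 ± 0.33, adjusted p = 0.014). Genes of the response to lack of amino acids and to endoplasmic reticulum stress were lower. Among its members, 0 of 16 tested genes rose, 5 fell and 11 did not pass (0 and 6 adjusted over the list alone, camera adjusted p = 6.4e-05, adjusted p = 0.73 with an estimated correlation). Its leading genes were Trib3 (-2.35 ± 0.51, adjusted p = 0.0056) and Vldlr (-1.57 ± 0.23, adjusted p = 0.00017). In the glucocorticoid list, 0 of 10 tested genes rose, 1 fell and 9 did not pass (0 and 2 adjusted over the list alone, camera adjusted p = 0.025, adjusted p = 0.55 with an estimated correlation). The gene that fell was Errfi1 (-0.7 ± 0.14, adjusted p = 0.0025), which encodes an inhibitor of epidermal growth factor receptors. The NRF2 list lost its call without WSS array 1 (camera adjusted p = 0.19). The glucocorticoid list lost its call without static array 3 or WSS array 3 (camera adjusted p up to 0.11). Nqo1 lost its call without static array 1 or 3 or WSS array 1 (adjusted p up to 0.084). Without WSS array 1 the log2 fold change was 0.86 for Nqo1. Nqo1, Trib3, Vldlr and Errfi1 did not pass with only the arrays compared.

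In the blood stem cell list at 36 h, 2 of 16 tested genes rose, 0 fell and 14 did not pass (2 and 0 adjusted over the list alone, camera adjusted p = 0.41). Its median was 0.14, or -0.01 with median scaling. Gata2 and Kit rose, Gata2 (1.06 ± 0.23, adjusted p = 0.0063) and Kit (0.58 ± 0.17, adjusted p = 0.034). No call was made for Runx1 (0.08 ± 0.26) and Itga2b (-0.13 ± 0.22), with adjusted p of at least 0.77. Among laminar flow genes, 3 of 16 tested genes rose, 2 fell and 11 did not pass (3 and 3 adjusted over the list alone, camera adjusted p = 0.93). Thbd fell, Thbd (-1.63 ± 0.38, adjusted p = 0.01). Those that did not pass included Klf2 (0.85 ± 0.45), Klf4 (0.36 ± 0.25), Nos3 (0.04 ± 0.21) and Cyp1b1 (-0.57 ± 0.19), with adjusted p of at least 0.067. Among prostaglandin genes, 0 of 9 tested genes rose, 1 fell and 8 did not pass (0 and 1 adjusted over the list alone, camera adjusted p = 0.52). The gene that fell was the thromboxane receptor gene Tbxa2r (-1.18 ± 0.19, adjusted p = 0.00031). Panel genes of prostaglandin synthesis, endothelium and cyclic AMP signalling that did not pass were Ptges (0.27 ± 0.25), Hpgd (-0.21 ± 0.26), Cdh5 (-0.09 ± 0.26), Pecam1 (-0.08 ± 0.21) and Crem (0.27 ± 0.15), with adjusted p of at least 0.3. Gata2 lost its call without static array 1 (adjusted p = 0.05). Kit lost its call without static array 1, 2 or 3 or WSS array 2 or 3 (adjusted p up to 0.16). Thbd lost its call without static array 3 or WSS array 1 (adjusted p up to 0.07). Log2 fold changes with no background correction were Gata2 0.65 and Tbxa2r -0.6, and Tbxa2r had -0.73 with an offset of 50. Gata2, Kit and Thbd did not pass with only the arrays compared. Kit did not pass with array weights.

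At 36 h 1146 of 12226 genes passed, 569 higher and 577 lower, which is 49.7% higher, or 36.4% with median scaling. All arrays of one group lay beyond those of the other for 2937 genes, or 24%, against 10% by chance. Fitted on the 6 arrays compared alone, 127 genes passed. Of the 34 passing genes named for this comparison 13 passed in that fit. Without static array 1 the number was 626, and without static array 3 it was 611.

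**Figure D2:**
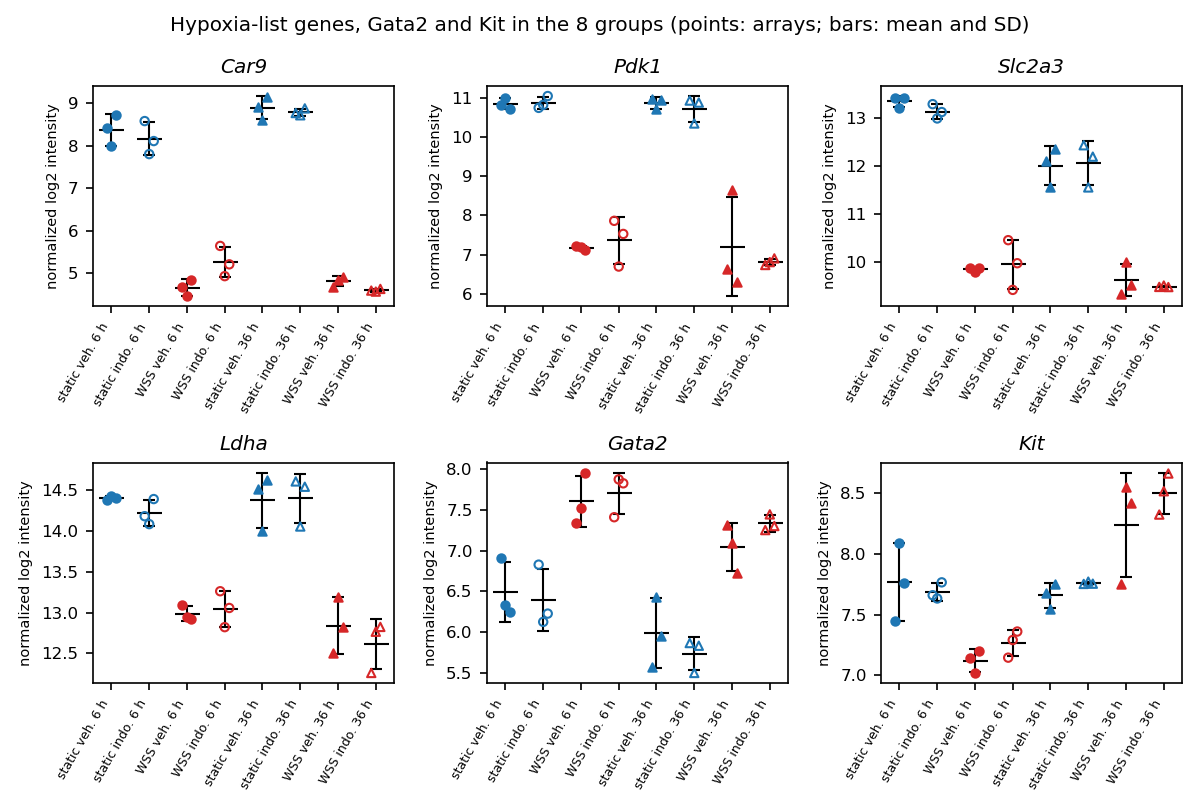
Normalized log2 signal (vertical axis, log2 units) of Car9, Pdk1, Slc2a3, Ldha, Gata2 and Kit in each of the 24 arrays, by group of 3 (horizontal axis), with the group mean and SD as bars. Car9 and Pdk1 are lower in each WSS group than in its static group, as in vehicle at 6 h (-3.71 and -3.68) and at 36 h (-4.08 and -3.69).

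With indomethacin throughout, hypoxia and glycolysis genes were lower under 6 h of flow. Within the list, 0 of 15 tested genes rose, 15 fell and 0 did not pass (0 and 15 adjusted over the list alone, camera adjusted p = 3.6e-26, adjusted p = 0.089 with an estimated correlation). The largest falls were in Pdk1 (-3.51 ± 0.37, adjusted p = 2.2e-06), Mgarp (-3.27 ± 0.43, adjusted p = 2.8e-05), Hspa1a (-3.22 ± 0.67, adjusted p = 0.0023) and Slc2a3 (-3.19 ± 0.24, adjusted p = 2.5e-08). The largest rises were in Gdf10 (2.2 ± 0.36, adjusted p = 0.00028), Acod1 (2.05 ± 0.4, at least 3.08-fold, adjusted p = 0.0014), Sct (1.88 ± 0.23, adjusted p = 1.7e-05) and Ccl5 (1.84 ± 0.51, at least 2.52-fold, adjusted p = 0.017). Gdf10 encodes a growth factor of the BMP family and Sct the hormone secretin. Immediate early genes were lower. By gene, 0 of 15 tested genes rose, 8 fell and 7 did not pass (0 and 11 adjusted over the list alone, camera adjusted p = 1.1e-05, adjusted p = 0.55 with an estimated correlation). They were led by Ier3 (-1.51 ± 0.27, adjusted p = 6e-04) and Fos (-1.23 ± 0.32, adjusted p = 0.01). NRF2 targets were higher. Counted singly, 5 of 14 tested genes rose, 0 fell and 9 did not pass (9 and 0 adjusted over the list alone, camera adjusted p = 0.0019, adjusted p = 0.75 with an estimated correlation). The largest rise was in the cystine transporter gene Slc7a11 (1.37 ± 0.34, adjusted p = 0.0092). Ccl5 lost its call without static array 1 or WSS array 3 (adjusted p up to 0.13). Fos lost its call without static array 1 or WSS array 2 (adjusted p up to 0.061). Without WSS array 3 the log2 fold change was 1.22 for Ccl5. With no background correction log2 fold changes were Acod1 1.17, Ccl5 1.07 and Slc7a11 0.7. With an offset of 50 they were Acod1 1.26, Ccl5 1.1 and Slc7a11 0.85. Ccl5 did not pass with median scaling or with the processed values.

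Targets of Wnt signalling were higher in that comparison. Of its members, 4 of 9 tested genes rose, 0 fell and 5 did not pass (6 and 0 adjusted over the list alone, camera adjusted p = 0.018, adjusted p = 0.71 with an estimated correlation). The largest rise was in the Wnt inhibitor gene Dkk1 (1.36 ± 0.18, at least 2.07-fold, adjusted p = 3.5e-05). In the glucocorticoid list, 0 of 10 tested genes rose, 1 fell and 9 did not pass (0 and 1 adjusted over the list alone, camera adjusted p = 0.039, adjusted p = 0.65 with an estimated correlation). The gene that fell was Errfi1 (-0.79 ± 0.14, adjusted p = 0.00055). Gata2 rose and Thbd fell, Gata2 (1.31 ± 0.23, adjusted p = 0.00066) and Thbd (-1.9 ± 0.38, adjusted p = 0.0019), and no call was made for Kit (-0.42 ± 0.17, adjusted p = 0.091). In the erythroid list, 0 of 16 tested genes rose, 1 fell and 15 did not pass (0 and 1 adjusted over the list alone, camera adjusted p = 0.069). Its mean level was 8.76 ± 1.29 (SD) over the 3 WSS indomethacin arrays, the lowest being 7.27 in array 2, and 9.45 ± 0.23 in WSS vehicle arrays. The Wnt list lost its call without static array 3 (camera adjusted p = 0.14). The glucocorticoid list lost its call without static array 3 or WSS array 2 (camera adjusted p up to 0.1). Dkk1 had a log2 fold change of 0.66 with no background correction and 0.75 with an offset of 50.

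With the drug 2170 genes passed at 6 h, 1150 higher and 1020 lower, which is 53% higher, or 40.7% with median scaling. The groups did not overlap in 4918 of 12226 genes, or 40.2%, against 10% by chance. The number was 4884 with array weights. It was 1181 without static array 1, 1198 without WSS array 2 and 1261 without WSS array 3. Normalized without that WSS array 2, an alternative chosen after seeing the data, it was 1195.

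At 36 h with indomethacin, hypoxia and glycolysis genes were lower under flow. Of these, 0 of 15 tested genes rose, 15 fell and 0 did not pass (0 and 15 adjusted over the list alone, camera adjusted p = 3.4e-32, adjusted p = 0.056 with an estimated correlation). The largest falls were in Mgarp (-4.6 ± 0.43, adjusted p = 2.4e-07), Car9 (-4.19 ± 0.2, at least 13.1-fold, adjusted p = 1.6e-11), Slc7a3 (-4.01 ± 0.67, adjusted p = 0.00048) and Pdk1 (-3.91 ± 0.37, adjusted p = 3.8e-07). The largest rises were in Marco (2.15 ± 0.32, at least 3.14-fold, adjusted p = 0.00011), Dct (1.83 ± 0.36, adjusted p = 0.0021), Arap2 (1.73 ± 0.2, adjusted p = 5.2e-06) and Zfp365 (1.71 ± 0.3, adjusted p = 0.00069). Slc7a3 encodes a transporter of basic amino acids and Marco a scavenger receptor of macrophages. Targets of p53 were higher. In that list, 6 of 9 tested genes rose, 0 fell and 3 did not pass (8 and 0 adjusted over the list alone, camera adjusted p = 1.1e-05, adjusted p = 0.32 with an estimated correlation). The leading members were Cdkn1a (1.41 ± 0.22, adjusted p = 0.00026) and Trp53inp1 (1.16 ± 0.17, adjusted p = 0.00011). The amino acid and endoplasmic reticulum stress list was lower. Among its members, 1 of 16 tested genes rose, 9 fell and 6 did not pass (1 and 11 adjusted over the list alone, camera adjusted p = 1.3e-06, adjusted p = 0.67 with an estimated correlation). Examples were Trib3 (-3.56 ± 0.51, adjusted p = 9e-05) and Chac1 (-2.38 ± 0.46, adjusted p = 0.0018). Mesenchyme genes were lower. Within the list, 0 of 15 tested genes rose, 4 fell and 11 did not pass (0 and 4 adjusted over the list alone, camera adjusted p = 0.015, adjusted p = 0.65 with an estimated correlation). The largest fall was in Lox (-2.82 ± 0.36, adjusted p = 1.9e-05). Among markers of neurons and neural crest, 3 of 9 tested genes rose, 1 fell and 5 did not pass (4 and 1 adjusted over the list alone, camera adjusted p = 0.16). The mesenchyme list lost its call without WSS array 2 (camera adjusted p = 0.062). Log2 fold changes with no background correction were Car9 -2.74 and Marco 1.16, and Marco had 1.3 with an offset of 50.

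Wnt targets were higher there. By gene, 3 of 9 tested genes rose, 0 fell and 6 did not pass (4 and 0 adjusted over the list alone, camera adjusted p = 0.011, adjusted p = 0.71 with an estimated correlation). Lef1, a factor of Wnt signalling, led them, Lef1 (1.04 ± 0.2, adjusted p = 0.0018). Immediate early genes were lower. Counted singly, 0 of 15 tested genes rose, 3 fell and 12 did not pass (0 and 7 adjusted over the list alone, camera adjusted p = 0.00093, adjusted p = 0.71 with an estimated correlation). The largest fall was in Ier3 (-1.52 ± 0.27, adjusted p = 0.00076). In the cholesterol synthesis list, 0 of 13 tested genes rose, 1 fell and 12 did not pass (0 and 3 adjusted over the list alone, camera adjusted p = 0.039, adjusted p = 0.9 with an estimated correlation). The gene that fell was Lss (-0.66 ± 0.19, adjusted p = 0.029). In the glucocorticoid list, 0 of 10 tested genes rose, 3 fell and 7 did not pass (0 and 3 adjusted over the list alone, camera adjusted p = 0.021, adjusted p = 0.55 with an estimated correlation). Gata2 and Kit rose and Thbd fell, Gata2 (1.6 ± 0.23, adjusted p = 1e-04), Kit (0.74 ± 0.17, adjusted p = 0.007) and Thbd (-1.68 ± 0.38, adjusted p = 0.0072). In total 1324 genes passed, 617 higher and 707 lower, which is 46.6% higher, or 37.8% with median scaling and 35.8% on the 6 arrays alone. The groups did not overlap in 3415 genes, or 27.9%, against 10% by chance. On the 6 arrays alone the number was 709, and it was 776 without static array 1 and 736 without WSS array 1. The cholesterol list lost its call without static array 1 or 3 or WSS array 2 or 3 (camera adjusted p up to 0.27). The glucocorticoid list lost its call without static array 2 or WSS array 3 (camera adjusted p up to 0.065). With fry the adjusted p was 0.19 for the cholesterol list. Lss lost its call without static array 1 or 3 or WSS array 1, 2 or 3 (adjusted p up to 0.18). Without static array 1 the log2 fold change was -0.43 for Lss. Log2 fold changes with no background correction were Lef1 0.51 and Gata2 0.99, and Lef1 had 0.61 with an offset of 50. Lss did not pass with only the arrays compared.

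Whether indomethacin changed the response to flow was tested as the difference of the flow effects with and without it. For Gata2 the difference was 0.2 ± 0.33 at 6 h (95% interval -0.49 to 0.89) and 0.54 ± 0.33 at 36 h (-0.14 to 1.23). It was 0.23 ± 0.24 and 0.16 ± 0.24 for Kit, 0.43 ± 0.64 and -0.68 ± 0.64 for Klf2, and 0.21 ± 0.37 and 0.34 ± 0.37 for Runx1. None of these passed. By limma 0 genes passed at 6 h and 0 at 36 h, with 485 and 513 genes at an unadjusted p under 0.05, against 611 by chance. The smallest p-values at 6 h were those of C1qbp (-0.64 ± 0.15), Prom1 (0.78 ± 0.19) and Sclt1 (-0.97 ± 0.24), with adjusted p of at least 1. At 36 h they were those of Fam222a (-1.56 ± 0.28), Crebbp (1.2 ± 0.23) and Fcgr3 (-1.22 ± 0.25), with adjusted p of at least 0.17. With array weights 1 gene passed at 6 h. At 36 h 3 passed with the deposited processed values, and 2 without WSS vehicle array 1 or 3.

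Erythroid genes had lower flow effects with the drug as a list at 6 h, with a median of -1.21. Of its members, 0 of 16 tested genes had a higher flow effect with the drug, 0 a lower one and 16 did not pass (0 and 0 adjusted over the list alone, camera adjusted p = 3.1e-06, adjusted p = 0.71 with an estimated correlation). WSS indomethacin array 2 had the lowest mean level of the list in its group, 7.27, and with fry the adjusted p was 0.36. Without that array the median was -0.38. At 36 h immediate early genes had a median of -0.25. Of these, 0 of 15 tested genes had a higher flow effect with the drug, 0 a lower one and 15 did not pass (0 and 0 adjusted over the list alone, camera adjusted p = 0.039, adjusted p = 0.8 with an estimated correlation). Wnt targets had a median of 0.31. In that list, 0 of 9 tested genes had a higher flow effect with the drug, 0 a lower one and 9 did not pass (0 and 0 adjusted over the list alone, camera adjusted p = 0.047, adjusted p = 0.75 with an estimated correlation). The Wnt call was also lost with the processed values (camera adjusted p = 0.058). The immediate early median was -0.15 without WSS vehicle array 1 and -0.4 without WSS indomethacin array 1. For Wnt targets it was 0.2 to 0.21 without static vehicle array 2, static indomethacin array 3, WSS vehicle array 1 or 3 or WSS indomethacin array 1. The immediate early list lost its call without static vehicle array 1 or 2 or static indomethacin array 1 or 3 or WSS vehicle array 1 or 2 or WSS indomethacin array 2 or 3 (camera adjusted p up to 0.31). The Wnt list lost its call without static vehicle array 1 or 2 or static indomethacin array 2 or 3 or WSS vehicle array 1 or 3 or WSS indomethacin array 1 or 3 (camera adjusted p up to 0.28). With fry the adjusted p was 0.44 for the immediate early list and 0.44 for the Wnt list.

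Across genes, which are not independent replicates, the flow effects with and without indomethacin correlated at r = 0.84 (Spearman 0.8) at 6 h and r = 0.77 (Spearman 0.66) at 36 h. These comparisons shared no arrays. At 6 h 1728 genes passed in both, all in the same direction. Of the 1728 genes, 874 were higher in both where independent lists would share 173.1, and 854 lower where they would share 146.2. At 36 h 653 passed in both, 651 in the same direction, with 274 higher against 28.7 and 377 lower against 33.4. Car9, Pdk1, Mgarp and Gata2 passed in each of the flow comparisons.

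**Figure D3:**
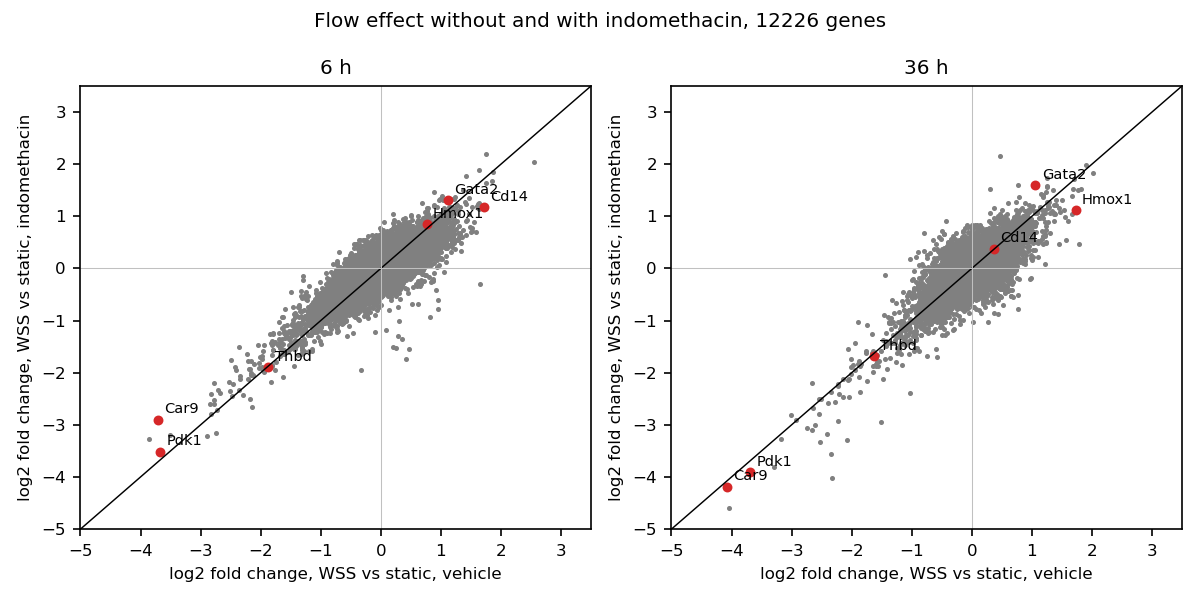
Each point is 1 of 12226 genes, with the log2 fold change of WSS against static in vehicle (horizontal axis) and with indomethacin (vertical axis), at 6 h and at 36 h in separate panels. The values run together along the diagonal, with r = 0.84 at 6 h and 0.77 at 36 h.

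Indomethacin against vehicle was compared within each flow state. Under flow at 6 h panel genes lay between -0.46 ± 0.38 for Thbd and 0.31 ± 0.21 for Nos3, and none passed. By limma 0 genes passed, with 357 at an unadjusted p under 0.05. The smallest p-values were those of Trmt2b (0.76 ± 0.16), Bmx (-1.05 ± 0.25) and Gnat3 (-0.69 ± 0.16), with adjusted p of at least 1. Erythroid genes were lower as a list. Among its members, 0 of 16 tested genes rose, 0 fell and 16 did not pass (0 and 1 adjusted over the list alone, camera adjusted p = 3.1e-06, adjusted p = 0.71 with an estimated correlation). Their mean level was 8.76 ± 1.29 (SD) in WSS indomethacin arrays, lowest at 7.27 in array 2, and 9.45 ± 0.23 in WSS vehicle arrays. Genes of skeletal muscle progenitors were lower as a list. Within the list, 0 of 8 tested genes rose, 0 fell and 8 did not pass (0 and 0 adjusted over the list alone, camera adjusted p = 0.047, adjusted p = 0.75 with an estimated correlation). The deposited processed values and array weights each gave 2 genes. The erythroid list lost its call without indomethacin array 2 (camera adjusted p = 0.97). The skeletal muscle list lost its call without vehicle array 1 or 3 or indomethacin array 2 or 3 (camera adjusted p up to 0.75). With fry the adjusted p was 0.43 for the erythroid list and 0.54 for the skeletal muscle list.

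Under flow at 36 h 1 gene was lower with indomethacin, Fcgr3 (-1.16 ± 0.18, at least 1.95-fold, adjusted p = 0.022), which encodes an Fc receptor of myeloid cells. In addition 5 lists were lower, although 0 members rose or fell alone, over all genes or adjusted over the list alone. They had 15 tested immediate early genes, 15 macrophage, 18 endothelial, 15 hypoxia and 16 amino acid and endoplasmic reticulum stress genes. The camera adjusted p was 0.0014 (adjusted p = 0.71 with an estimated correlation) for immediate early genes and 0.0084 (adjusted p = 0.8 with an estimated correlation) for macrophage genes. For endothelial and hypoxia genes it was 0.047 (adjusted p = 0.9 with an estimated correlation) and 0.00093 (adjusted p = 0.8 with an estimated correlation). For amino acid and endoplasmic reticulum stress genes it was 1.1e-05 (adjusted p = 0.71 with an estimated correlation). An unadjusted p under 0.05 was found for 698 genes, against 611 by chance. Normalized without WSS vehicle array 2, which stood apart and was left out after seeing the data, 0 genes passed. The number was also 0 without vehicle array 2 or indomethacin array 1 or 2, and 3 with the processed values. An offset of 50 gave 2 genes. The immediate early list lost its call without vehicle array 1 or indomethacin array 2 (camera adjusted p up to 0.14). The macrophage list lost its call without vehicle array 1 or 3 (camera adjusted p up to 0.21). The endothelial list lost its call without vehicle array 1 or 2 or indomethacin array 2 or 3 (camera adjusted p up to 0.74). The hypoxia list lost its call without vehicle array 2 (camera adjusted p = 0.69). The amino acid stress list lost its call without vehicle array 1 (camera adjusted p = 0.21). With fry the adjusted p was 0.22 for the immediate early list, 0.45 for the macrophage list, 0.6 for the endothelial list, 0.42 for the hypoxia list and 0.17 for the amino acid stress list. Fcgr3 lost its call without vehicle array 1, 2 or 3 or indomethacin array 1 or 2 (adjusted p up to 0.15). Fcgr3 had a log2 fold change of -0.56 with no background correction and -0.65 with an offset of 50. It did not pass with no background correction, only the arrays compared or array weights.

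In static culture at 6 h 0 genes passed by limma, with 804 at an unadjusted p under 0.05, against 611 by chance. With array weights 95 passed. The smallest p-values were those of Chst2 (-1.06 ± 0.21), Lcn10 (-0.7 ± 0.14, at least 1.2-fold) and Cbfa2t1h (0.74 ± 0.16), with adjusted p of at least 0.25. At 36 h 6 genes passed in static culture, with 688 at an unadjusted p under 0.05, against 611 by chance. Plcb4, a phospholipase gene, and Haus2, a spindle protein gene, rose, Plcb4 (1.09 ± 0.19, at least 1.66-fold, adjusted p = 0.019) and Haus2 (0.99 ± 0.16, at least 1.63-fold, adjusted p = 0.019). The coactivator gene Crebbp, the endothelin gene Edn3, Ralgapa1 and Tmem72 fell, Crebbp (-0.99 ± 0.16), Edn3 (-0.98 ± 0.15, at least 1.25-fold), Ralgapa1 (-0.79 ± 0.14, at least 1.48-fold) and Tmem72 (-0.79 ± 0.13, at least 1.2-fold), with adjusted p of at most 0.028. No list passed in static culture. The number at 36 h was 0 with median scaling, and 3 with a stricter filter on dim probes. It was 3 without vehicle array 1 or indomethacin array 1, and 0 without indomethacin array 2 or 3. Plcb4 and Haus2 lost calls without vehicle array 1 or 2 or indomethacin array 1, 2 or 3 (adjusted p up to 0.14 and 0.13). Crebbp lost its call without vehicle array 2 or indomethacin array 2 or 3 (adjusted p up to 0.11). Edn3 lost its call without vehicle array 3 or indomethacin array 2 or 3 (adjusted p up to 0.11). Ralgapa1 lost its call without vehicle array 1 or 2 or indomethacin array 1, 2 or 3 (adjusted p up to 0.23). Tmem72 lost its call without vehicle array 1 or 3 or indomethacin array 2 or 3 (adjusted p up to 0.14). Log2 fold changes with no background correction were Plcb4 0.52, Haus2 0.46, Crebbp -0.48, Edn3 -0.56, Ralgapa1 -0.36 and Tmem72 -0.41. With an offset of 50 they were Plcb4 0.6, Haus2 0.55, Crebbp -0.58, Edn3 -0.48, Ralgapa1 -0.43 and Tmem72 -0.38. For Haus2 the log2 fold change was 1.49 with the processed values. Plcb4, Haus2, Crebbp, Edn3, Ralgapa1 and Tmem72 did not pass with no background correction, an offset of 50, median scaling, only the arrays compared or trend and robust fitting. Plcb4 and Edn3 did not pass with the processed values.

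The flow effect in vehicle differed between 6 h and 36 h, by the interaction test, in 1440 genes, 777 with a higher effect at 36 h and 663 with a lower one. An unadjusted p under 0.05 was found for 3448 genes. The largest upward differences were in Aire (2.77 ± 0.3, adjusted p = 8.1e-05), Dct (2.72 ± 0.51, adjusted p = 0.0027), Foxb1 (2.46 ± 0.31, adjusted p = 0.00027) and Phxr4 (2.42 ± 0.47, adjusted p = 0.003). The largest downward differences were in Gbp2 (-2.43 ± 0.32, adjusted p = 0.00029), Trav9n-4 (-2.27 ± 0.41, adjusted p = 0.0019), Car3 (-2.21 ± 0.32, adjusted p = 0.00072) and Acod1 (-2.2 ± 0.56, adjusted p = 0.017). Aire is the autoimmune regulator, Foxb1 a transcription factor, Gbp2 a guanylate-binding protein induced by interferon and Car3 a carbonic anhydrase. Kit, lower under flow at 6 h and higher at 36 h, differed between the times, Kit (1.23 ± 0.24, adjusted p = 0.0033). No difference was called for Gata2 (-0.05 ± 0.33), Klf2 (0.82 ± 0.64) and Runx1 (-0.1 ± 0.37), with adjusted p of at least 0.42. Acod1 lost its call without 6 h WSS array 1 (adjusted p = 0.052). Log2 fold changes with no background correction were Aire 1.61, Dct 1.7, Foxb1 1.5, Gbp2 -1.26, Trav9n-4 -1.18 and Acod1 -1.25. With an offset of 50 they were Aire 1.79, Gbp2 -1.52 and Trav9n-4 -1.39. Acod1 did not pass with array weights.

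Immediate early genes had a median difference of 0.45 between the times. By gene, 4 of 15 tested genes had a higher flow effect at 36 h, 0 a lower one and 11 did not pass (4 and 0 adjusted over the list alone, camera adjusted p = 0.029, adjusted p = 0.8 with an estimated correlation). Leading the list were Fosb (1.91 ± 0.59, adjusted p = 0.039) and Fos (1.47 ± 0.45, adjusted p = 0.036). Targets of p53 had a median difference of 0.83. Counted singly, 5 of 9 tested genes had a higher flow effect at 36 h, 0 a lower one and 4 did not pass (5 and 0 adjusted over the list alone, camera adjusted p = 0.0023, adjusted p = 0.71 with an estimated correlation). The largest difference was in Mdm2 (1.3 ± 0.25, adjusted p = 0.003), which encodes a protein that restrains p53. In the hypoxia list, 2 of 15 tested genes had a higher flow effect at 36 h, 0 a lower one and 13 did not pass (2 and 0 adjusted over the list alone, camera adjusted p = 0.73). The median was -0.01 and the mean 0.16, with the test towards higher values. The largest difference there was in Ddit4 (1.96 ± 0.3, adjusted p = 0.00081), a stress-induced inhibitor of growth signalling. The immediate early list lost its call without 6 h static array 1 or 6 h WSS array 2 or 36 h static array 1 or 2 or 36 h WSS array 1 (camera adjusted p up to 0.11). With fry the adjusted p was 0.071 for the immediate early list. Fosb lost its call without 6 h static array 1, 2 or 3 or 6 h WSS array 1, 2 or 3 or 36 h static array 1 or 3 or 36 h WSS array 1 or 2 (adjusted p up to 0.11). Fos lost its call without 6 h static array 1 or 3 or 6 h WSS array 1, 2 or 3 or 36 h static array 1 or 3 or 36 h WSS array 1 or 2 (adjusted p up to 0.1). Fosb and Fos did not pass with no filter on dim probes. Fosb did not pass with only the arrays compared. Fos did not pass with median scaling.

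Across genes the flow effects at 6 h and 36 h (no shared arrays) correlated at r = 0.33 (Spearman 0.24). Of 428 genes passing at both times, 365 changed the same way and 63 oppositely. At both times 119 were higher, against 85.6 for independent lists, and 246 lower, against 82.7. Fisher's exact p (0.00012 and 4.5e-65) treats dependent genes as independent. At least 1 direction of the overlap no longer passed without static array 3 (r = 0.31) or WSS array 1 (r = 0.27) at 36 h. The number of genes whose flow effect differed was 954 on the 12 arrays alone, and 912 normalized without WSS vehicle array 2 at 36 h. It was 835 without static array 3 at 6 h, 849 without WSS array 1 at 6 h and 913 without WSS array 2 at 36 h.

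Time in static culture without drug was compared as background to the flow effects. The largest rises from 6 h to 36 h were in Lrrc17 (4.2 ± 0.19, adjusted p = 3.1e-12), Hopx (3.49 ± 0.42, adjusted p = 8.8e-07), Mgp (3.39 ± 0.25, adjusted p = 1.8e-09) and Col8a2 (3.33 ± 0.22, adjusted p = 6.8e-10). The largest falls were in Sall4 (-4.3 ± 0.25, adjusted p = 1.2e-10), Igdcc3 (-3.47 ± 0.2, adjusted p = 1.3e-10), Slc4a1 (-3.3 ± 0.69, adjusted p = 0.00046) and Nktr (-3.3 ± 0.28, adjusted p = 1.1e-08). Mgp is a matrix protein that limits calcification, Col8a2 a collagen, Sall4 a transcription factor of early embryonic cells and Slc4a1 the anion exchanger of red cells. Mesenchyme genes were higher. Of its members, 12 of 15 tested genes rose, 0 fell and 3 did not pass (12 and 0 adjusted over the list alone, camera adjusted p = 0.00036, adjusted p = 0.28 with an estimated correlation). Its leading genes were Lum (3.04 ± 0.36, adjusted p = 7.9e-07) and Lox (2.79 ± 0.36, adjusted p = 1.9e-06). Genes of urogenital epithelium were lower. Of these, 0 of 11 tested genes rose, 9 fell and 2 did not pass (0 and 9 adjusted over the list alone, camera adjusted p = 0.0062, adjusted p = 0.25 with an estimated correlation). The keratin genes led them, Krt18 (-2.42 ± 0.36, adjusted p = 1e-05) and Krt8 (-2.33 ± 0.48, adjusted p = 0.00037). In total 6228 genes passed, 3174 higher and 3054 lower. The groups did not overlap in 6954 genes, or 56.9%, against 10% by chance. For Col8a2 the log2 fold change was 2.1 with no background correction.

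Genes of skeletal muscle progenitors were higher at 36 h. In that list, 5 of 8 tested genes rose, 0 fell and 3 did not pass (5 and 0 adjusted over the list alone, camera adjusted p = 0.021, adjusted p = 0.73 with an estimated correlation). They were led by the acetylcholine receptor gene and myogenin, Chrna1 (3.09 ± 0.27, adjusted p = 1.8e-08) and Myog (2.56 ± 0.26, adjusted p = 1.2e-07). Targets of PPAR factors, which regulate fat metabolism, were higher. Among its members, 5 of 8 tested genes rose, 0 fell and 3 did not pass (5 and 0 adjusted over the list alone, camera adjusted p = 0.021, adjusted p = 0.73 with an estimated correlation). The leading members were Angptl4 (2.91 ± 0.26, adjusted p = 2.1e-08) and Acaa2 (1.73 ± 0.2, adjusted p = 4.1e-07). In the erythroid list, 0 of 16 tested genes rose, 8 fell and 8 did not pass (0 and 7 adjusted over the list alone, camera adjusted p = 0.12). In the macrophage list, 8 of 15 tested genes rose, 0 fell and 7 did not pass (10 and 0 adjusted over the list alone, camera adjusted p = 0.052). Runx1 and Klf2 rose, Runx1 (0.72 ± 0.26, adjusted p = 0.027) and Klf2 (1.15 ± 0.45, adjusted p = 0.038). No call was made for Gata2 (-0.51 ± 0.23) and Kit (-0.11 ± 0.17), with adjusted p of at least 0.074. Runx1 lost its call without 6 h array 2 or 3 or 36 h array 3 (adjusted p up to 0.21). Klf2 lost its call without 6 h array 1 or 2 or 36 h array 1 or 2 (adjusted p up to 0.15). Without 36 h array 3 the log2 fold change was 0.39 for Runx1. Runx1 and Klf2 did not pass with median scaling. Runx1 did not pass with only the arrays compared. Klf2 did not pass with no background correction, no filter on dim probes or trend and robust fitting.

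**Figure D4:**
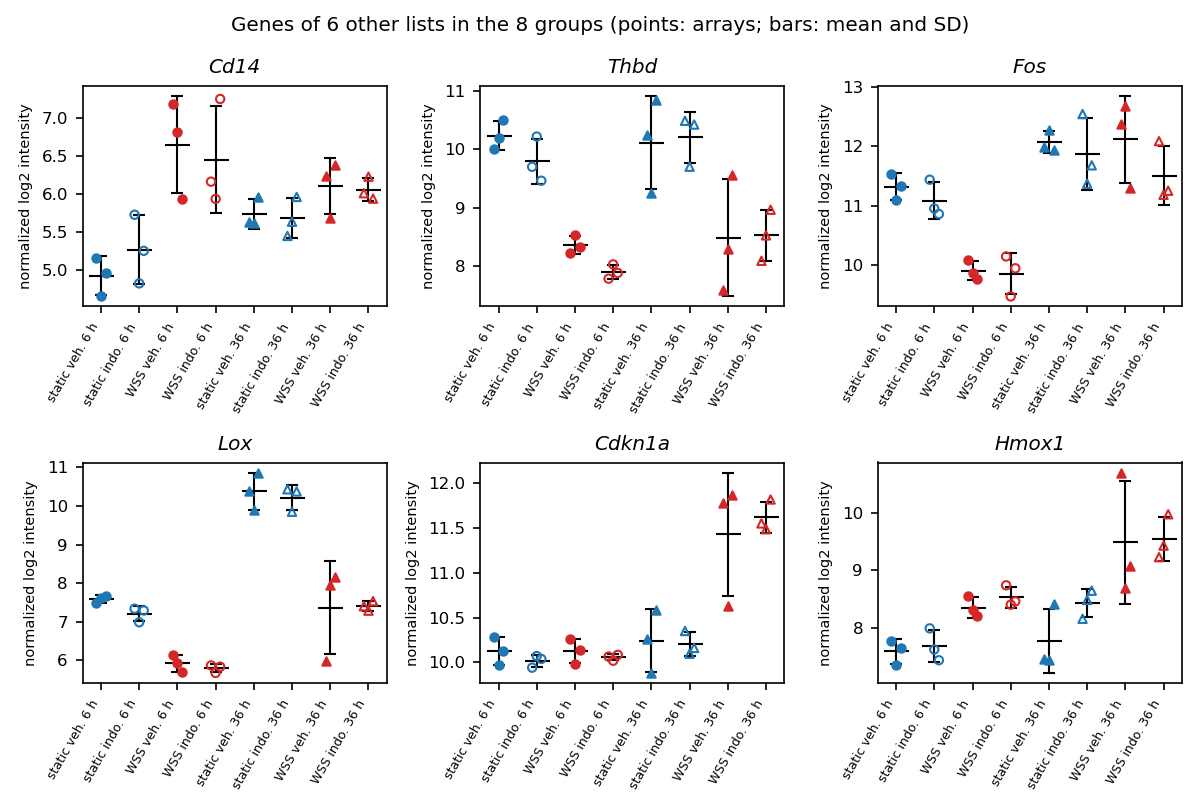
Normalized log2 signal (vertical axis, log2 units) of Cd14, Thbd, Fos, Lox, Cdkn1a and Hmox1 in each of the 24 arrays, by group of 3 (horizontal axis), with the group mean and SD as bars. Thbd is lower in the WSS vehicle group than in the static one at 6 h (-1.87) and at 36 h (-1.63), and Lox is higher at 36 h than at 6 h in static vehicle (2.79).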

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

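The splits of the flow by drug interaction that reassign drug labels within each flow state were chosen after a first version, which reassigned flow labels within each drug arm, had been seen. The flow effect in vehicle differed between 6 h and 36 h in 1440 genes by the interaction test of limma. The largest differences, as the log2 flow effect at 36 h minus that at 6 h, were 2.77 for Aire, 2.72 for Dct, 2.46 for Foxb1 and 2.42 for Phxr4. Downward they were -2.43 for Gbp2, -2.27 for Trav9n-4, -2.21 for Car3 and -2.2 for Acod1, whose call was lost without WSS array 1 at 6 h (adjusted p = 0.052). Kit differed by 1.23. The immediate early list differed by a median of 0.45 (adjusted p = 0.8 with an estimated correlation) and the p53 list by 0.83 (adjusted p = 0.71 with an estimated correlation). The immediate early call was also lost with fry (adjusted p = 0.071) and without each of 5 single arrays (camera adjusted p up to 0.11). By camera the flow effect also differed with the drug for the erythroid list at 6 h (median -1.21), and for the immediate early list (-0.25) and the Wnt list (0.31) at 36 h, although 0 members passed. With an estimated correlation the adjusted p was 0.71, 0.8 and 0.75, and with fry it was 0.36, 0.44 and 0.44. WSS indomethacin array 2 at 6 h had an erythroid list level of 7.27, in a group with a mean of 8.76 and an SD of 1.29, and without it the median was -0.38. Both calls at 36 h were lost without single arrays, at a camera adjusted p of up to 0.31 and 0.28. Without single arrays their medians were -0.15 (without WSS vehicle array 1) to -0.4 (without WSS indomethacin array 1) for the immediate early list, and as low as 0.2 for the Wnt list (without static vehicle array 2, WSS vehicle array 3 or WSS indomethacin array 1).

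Probes with no gene symbol listed were outside the comparisons by gene. Of 3009 such detected probes, 1036 passed for WSS against static in vehicle at 6 h, 316 higher and 720 lower, and 117 passed at 36 h, 45 higher and 72 lower.

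Other splits of the same arrays were fitted for each comparison. The 10 splits of 3 arrays against 3 are too few for a share under 0.05. For WSS against static the real number and the highest of the other splits were 3592 and 0 in vehicle at 6 h, 1146 and 114 in vehicle at 36 h, 2170 and 0 with indomethacin at 6 h, and 1324 and 30 with indomethacin at 36 h. For indomethacin against vehicle they were 0 and 4 under flow at 6 h, 1 and 14 under flow at 36 h, 0 and 1 in static culture at 6 h, and 6 and 1 in static culture at 36 h. For time in static culture they were 6228 and 0. For the flow by time interaction 8 of 100 splits gave at least as many genes as the real 1440, and the highest other split gave 3383 genes. A split that turns or mixes the flow labels of 1 time point counts the flow effect itself as an interaction, so these splits do not show whether chance can be excluded. For the flow by drug interaction the real number was 0 at both times, which all 100 of 100 splits reach whatever the data, so they test nothing there. The highest other split gave 3 at 6 h and 283 at 36 h, and no cause of the 283 was tested.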

How the results depend on the processing

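Normalization without WSS vehicle array 2 at 36 h or WSS indomethacin array 2 at 6 h was chosen after seeing the data. For WSS against static, 3592 genes passed in vehicle at 6 h and 3264 to 4711 under the settings that kept all arrays, and 6228 and 5696 to 7009 for time in static culture. In vehicle at 36 h only the arrays compared gave 127 genes in place of 1146, and with indomethacin at 36 h 709 in place of 1324. With indomethacin at 6 h array weights gave 4884 in place of 2170, and normalization without WSS array 2 gave 1195. Static array 2 there weighed 4.46 and arrays 1 and 3 0.73 and 0.55, so their weighted mean rested mostly on array 2. For indomethacin under WSS at 6 h the processed values and array weights gave 2 genes each in place of 0. At 36 h, in place of 1, the number was 0 with no background correction, with only the arrays compared, with array weights and normalized without WSS vehicle array 2, 2 with an offset of 50 and 3 with the processed values. In static culture array weights, with the same 4.46, gave 95 genes at 6 h in place of 0. At 36 h, in place of 6, it was 0 with no background correction, an offset of 50, median scaling, only the arrays compared or trend and robust fitting, and 3 with a stricter filter. For the flow by drug interaction, in place of 0, array weights gave 1 gene at 6 h and the processed values 3 at 36 h. For the flow by time interaction only the arrays compared gave 954 in place of 1440, and normalization without WSS vehicle array 2 gave 912. A fit of only the arrays compared has fewer samples, but gave 3605 genes in vehicle at 6 h. WSS vehicle arrays spread more at 36 h than at 6 h in most lists (hypoxia SD 0.43 and 0.09). A variance shared by all groups may be too small there, and no cause was tested. List calls numbered 40, and 0 with an estimated correlation. With fry they numbered 49, of which 27 were among the 40.

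Without each array in turn, the number of passing genes for WSS against static was 2586 to 3047 in vehicle at 6 h, 611 to 1246 in vehicle at 36 h, 1181 to 2042 with indomethacin at 6 h and 736 to 1181 with indomethacin at 36 h. For indomethacin it was 0 to 0 under WSS at 6 h, 0 to 1 under WSS at 36 h, 0 to 0 in static culture at 6 h and 0 to 4 at 36 h. It was 0 to 0 and 0 to 2 for the flow by drug interaction at 6 h and 36 h, 835 to 1434 for the flow by time interaction and 5460 to 5925 for time. List calls numbered 34 to 53. The correlation of flow effects with and without drug was 0.8 to 0.85 at 6 h and 0.7 to 0.76 at 36 h. Between 6 h and 36 h it was 0.27 to 0.39, and at least 1 direction of the overlap of calls no longer passed at 0.31 (without static array 3 at 36 h) and 0.27 (without WSS array 1 at 36 h). Of 197 gene results printed, 147 were called. Of these 103 kept their call under every setting and without each array, 44 lost it under at least 1, and 0 reversed. The log2 fold change moved by over 1.5 times in 43 of the called results with no background correction, in 29 with an offset of 50, and in 1 each with median scaling and the processed values.

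With the replicate block the number of genes was 3814, 1374, 2339 and 1522 for WSS against static (vehicle at 6 h and 36 h, indomethacin at 6 h and 36 h). It was 0 and 2 for indomethacin under WSS, 0 and 4 in static culture, 0 and 0 for the flow by drug interaction, 1675 for flow by time and 6335 for time. Saa3 for WSS against static in vehicle at 6 h (adjusted p = 0.05), and Plcb4 (0.05), Ralgapa1 (0.091) and Tmem72 (0.05) for indomethacin in static culture at 36 h, did not pass with the block. Deviations of same-numbered arrays correlated at -0.226 to 0.362 (mean 0.096, against -0.048 for other numbers at the same time). Of 24 arrays 14 were closest to their own number, a hint of pairing from the data and not the design. Pairing was taken to need a correlation over 0.1 in all 36 pairs, which 21 reached, so the numbers were not taken to pair the samples. Real pairing could miss so strict a rule, so it stays open. The slide is not given by the files or labels, and slide as a block was not run. Signal over background limits what could be tested, since 21251 of 45281 probes were detected.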

Other observations

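The loss of listed cell types, oxygen or medium supply, more macrophages, shared arrays and the signs of list medians were tested only after the results they bear on had been seen. At 6 h of flow without drug, single genes of further groups also changed. In the cell cycle list, 4 of 18 tested genes rose, 1 fell and 13 did not pass (4 and 1 adjusted over the list alone, camera adjusted p = 0.2). It was led by Rrm2 (1.14 ± 0.12, adjusted p = 1.5e-06) and Tyms (1.14 ± 0.19, adjusted p = 0.00018), enzyme genes of nucleotide synthesis. In the cholesterol synthesis list, 1 of 13 tested genes rose, 6 fell and 6 did not pass (2 and 7 adjusted over the list alone, camera adjusted p = 0.09). Among Notch and arterial genes, 0 of 15 tested genes rose, 3 fell and 12 did not pass (0 and 2 adjusted over the list alone, camera adjusted p = 0.41). The Notch target gene Hes1 and the ligand gene Jag2 fell, Hes1 (-0.72 ± 0.21, adjusted p = 0.015) and Jag2 (-0.59 ± 0.19, adjusted p = 0.026). In the heat shock list, 0 of 10 tested genes rose, 2 fell and 8 did not pass (0 and 2 adjusted over the list alone, camera adjusted p = 0.88). The median was 0.24 and the mean -0.34, with the test towards higher values. Beside Hspa1a, the related gene Hspa1b (-2.18 ± 0.46, adjusted p = 0.0013) fell. Among Wnt targets, 4 of 9 tested genes rose, 1 fell and 4 did not pass (5 and 1 adjusted over the list alone, camera adjusted p = 0.087). The largest rise was in Dkk1 (1.46 ± 0.18, adjusted p = 8.1e-06). Hes1 lost its call without static array 1 or WSS array 1 (adjusted p up to 0.093). Jag2 lost its call without static array 2 or 3 or WSS array 1 or 3 (adjusted p up to 0.12). Jag2 had a log2 fold change of -0.27 with no background correction, -0.32 with an offset of 50 and -0.94 with median scaling. Dkk1 had 0.73 with no background correction and 0.83 with an offset of 50. Jag2 did not pass with no background correction.

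At 36 h of flow without drug, 2 of 9 tested Wnt targets rose, 1 fell and 6 did not pass (5 and 1 adjusted over the list alone, camera adjusted p = 0.33). The largest change was in Apcdd1 (0.9 ± 0.18, adjusted p = 0.0026), an inhibitor gene of Wnt signalling. The kidney development gene Ret (1.37 ± 0.23, adjusted p = 0.00067), the neural crest gene Sox10 (0.84 ± 0.19, adjusted p = 0.0088) and the somite gene Meox1 (-1.45 ± 0.45, adjusted p = 0.047) also changed. The chemokine gene Cxcl1 (-0.95 ± 0.25, adjusted p = 0.022) led the inflammatory list, of which 0 of 11 tested genes rose, 2 fell and 9 did not pass (0 and 3 adjusted over the list alone, camera adjusted p = 0.49). The median was 0.08 and the mean -0.1, with the test towards lower values. Sox10 lost its call without WSS array 3 (adjusted p = 0.059). Meox1 lost its call without static array 1, 2 or 3 or WSS array 1 or 3 (adjusted p up to 0.27). Cxcl1 lost its call without static array 1 or 3 or WSS array 3 (adjusted p up to 0.12). Without WSS array 3 the log2 fold change was -0.77 for Meox1 and -0.51 for Cxcl1. For Ret the log2 fold change was 0.88 with no background correction. Apcdd1, Sox10, Meox1 and Cxcl1 did not pass with only the arrays compared. Meox1 did not pass with the processed values, no filter on dim probes, trend and robust fitting or all detected probes.

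Hypoxia and glycolysis transcripts were lower under flow, by a median of -2.34 at 6 h in vehicle. The highest list median under 4 other scalings was -2.05, and the lowest of 10000 random lists matched on brightness was -0.53, which argues against scaling and array brightness as the cause. The lowest median of a listed cell type was -0.35, which argues against the loss of 1 such type with bright markers. The macrophage (5.98 in static arrays) and endothelial (6.49) lists were too dim to tell, and the germ cell list held 3 genes. The design changes shear and medium movement together, so shear and oxygen or medium supply cannot be told apart (laminar flow list median -0.14).

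Acod1, Ccl5, Clec4d, Cd14, Cxcl2, Lyz2 and Adgre1, chosen after their values were seen, rose by a median of 1.72 (SD 0.39 over the 7 transcripts) under 6 h of flow. Their median was 1.2 without WSS array 1, which had the highest mean level of both these transcripts (7.58) and the macrophage list (6.79) among the 6 arrays. More macrophages in the flow cultures cannot be told apart from a change within them. The macrophage list had a median of 0.09 (SD 0.71 over members), or -0.13 without that array, but it holds 3 of the 7 transcripts, and its mean level in static arrays was 5.98, where the lowest detected signals were 4.91 to 5.26 over all arrays. Scaling stays open, since the lowest median of the 7 transcripts under 4 other scalings was 0.91, as does an effect of flow on these transcripts, untested beyond the comparison itself.

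Genes changed by 6 h of flow tended to change in the same direction with time in static culture. Against time in static vehicle, the flow effect with indomethacin, which shares no array with it, gave r = 0.42 across genes, and 1279 of 1429 genes that passed in both (89.5%) had the same direction, which argues against shared arrays as the whole cause. With shared arrays, in vehicle, r was 0.5 where simulated arrays without effects also gave 0.5, and the covariance was 0.18 against 0.02. Over coding transcripts r was 0.38 (0.55 over others), and after a trend with brightness was removed 0.42. This argues against non-coding transcripts and a trend with gene brightness left after normalization as the whole cause. A trait of static 6 h arrays, the reference of both comparisons with the lowest average signal (409.7) and most probes detected (47.15%), stays open. Not all groups followed, since the medians of 11 of 31 lists had opposite signs, as for immediate early genes (-0.77 with flow and indomethacin, 0.24 with time) and hypoxia genes (-2.12 and 0.03), so what the shared direction reflects stays open, and other scalings were not tested for it.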
